A study of Homo sapiens with 9 samples.

How the data were processed

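Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where 2 DNA-binding proteins lie on the genome. Per the labels, chromatin was fixed with formaldehyde, precipitated with an antibody against ZEB1 or CTCF, and sequenced on an Illumina instrument. The series as used here holds 9 samples, of which 5 have a peak list. These are ZEB1 in unmodified MiaPaCa2 cells, ZEB1 in unmodified RKO cells, ZEB1 in a MiaPaCa2 clone named WT, ZEB1 in a MiaPaCa2 clone named delta-Repeat, and CTCF in unmodified MiaPaCa2 cells. The other 4 samples are input DNA from MiaPaCa2, RKO, PANC1 and CFPAC1 cells and were not analysed here. Neither clone has an input sample of its own in the series as used here.

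The submitters' processing notes name Bowtie2 2.2.6, SAMtools and MACS2 2.1.0.20150731, and the builds hg19 and GRCh37. Which input library served as the control of which peak list is not given in the sources used here. Each deposited list belongs to 1 sample, and whether reads of several libraries were pooled for it is not given in the sources used here. The deposited lists give for every peak a chromosome, a start, an end and a summit. The deposited fold enrichment at the summit is a linear ratio over the caller's background, as the authors' peak caller wrote it. The deposited p-value and q-value columns hold −log10 values, also from the authors' peak caller. The deposited score column equals 10 times the −log10 q of the same peak as a whole number, to within 1, in every peak of the 5 lists and was not used further. The fold and the −log10 q of a peak were used only to describe, rank or filter peaks within their own list, because a fold depends on the depth and the control of its sample. Read depth is unknown from the lists, and a deeper library yields more and weaker peaks.

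Peak lists were compared by position with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. The overlap code was tested on simulated lists, with bedtools 2.31.1 beside it, in which 500 overlaps had been planted in each of 3 comparisons, and all 500 were found each time. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Neighbouring peaks are not independent, and each condition has 1 sample with a peak list, so no interval or p-value here measures the spread between cultures. For each overlap the second list was placed at random 1000 times with the same widths on the same chromosomes. The smallest p this can give is 0.001. Places were drawn evenly along each chromosome, without regard to gaps in the assembly or to where peaks can be called. An excess over random placement therefore does not show that 2 lists meet more often than any 2 peak lists would. The length of a chromosome was taken as the largest peak end over the 5 lists. Each list was also divided into 4 classes of about equal size by fold, where class 1 is the weakest and class 4 the strongest. Fisher's exact tests across peaks were two-sided with Benjamini-Hochberg adjustment within each family of tests, and they describe these lists, not the conditions. A Mantel-Haenszel odds ratio over the 4 fold classes was used where strength could differ between chromosomes.

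Peaks named in the text followed rules fixed before the data were examined. These were the 10 peaks of highest fold in each list and, for each pair of lists compared, the 5 strongest peaks of each list with no overlap in the other. Other peaks, the division by chromosome, the dense windows and the distance from chromosome ends were chosen after the lists had been seen. The alternatives fixed beforehand were a stricter threshold (fold at least 5 and −log10 q at least 10), an overlap of 50% of both peaks, summits within 100 bp, and lists of equal length.

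Coordinates are those of the deposited lists (hg19), counted from 1. No hg19 genome or annotation was used here, so peaks are given by position and not by gene. The only gene table used names genes of the assembly GRCh38.p14, and it served for the names and the order of neighbouring genes. For this reason the planned results on peak position relative to genes, ZEB1 motifs, tandem motif arrays and gene lists near peaks were not run, and neither was the planned window of 20 kb around MIR200B. In place of that window, the strongest WT clone peak with no delta-Repeat clone peak was followed through all lists.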

Results

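ZEB1 is a zinc-finger transcription factor that represses epithelial genes and drives the epithelial-to-mesenchymal transition, and it is itself a target of the miR-200 family of microRNAs. CTCF is a zinc-finger protein that binds insulators and the borders of chromatin loops. ZEB1 was profiled in 4 samples and CTCF in 1. MiaPaCa2 is a cell line from a pancreatic ductal adenocarcinoma and RKO is a cell line from a colon carcinoma. Both clones came from MiaPaCa2 cells that had been electroporated with Cas9-nickase plasmids, and were isolated by dilution. The delta-Repeat clone had also received guide RNAs against a repeated region upstream of MIR200A and MIR200B, and the WT clone was its control. All ZEB1 samples used the same antibody. Both clones shared 1 lot of it, while the unmodified MiaPaCa2 and RKO cells each had a lot of their own. There was 1 sample with a peak list per condition, so no difference between conditions can be set against a spread between replicates.

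The ZEB1 lists held 4804 peaks in unmodified MiaPaCa2 cells, 7193 in RKO cells, 1515 in the WT clone and 2160 in the delta-Repeat clone, and the CTCF list held 31754. The authors' median fold enrichment was 6.53 in MiaPaCa2, 6.04 in RKO, 7.46 in the WT clone, 7.06 in the delta-Repeat clone and 10.8 for CTCF. Median peak width lay between 333 and 387 bp in all 5 lists. The stricter threshold left 2013, 2949, 786 and 1057 ZEB1 peaks in the same order, and 25545 CTCF peaks. Read depth was unknown, so the shorter clone lists do not by themselves show fewer bound sites. Joined across lists, the ZEB1 peaks made 9304 regions. Of these, 916 were in all 4 ZEB1 lists and 5923 were in 1 list only.

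Most of the strongest ZEB1 peaks recurred in every background. A peak on chromosome 16 from 90097285 to 90099860 had the highest fold of the MiaPaCa2 list, at 115. The peak at this place also ranked first in the WT clone with a fold of 81.2 and in the delta-Repeat clone with a fold of 78.2, and ranked second in RKO with a fold of 106. Among the 10 strongest peaks of each list, those found in all 3 other ZEB1 lists numbered 9 for MiaPaCa2, 8 for RKO, 8 for the WT clone and 9 for the delta-Repeat clone. They included peaks on chromosome 5 (68787961 to 68789356, MiaPaCa2 fold 64.1), chromosome 13 (114319193 to 114321438, fold 62.4) and chromosome 19 (11320459 to 11322795, fold 61.3).

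The comparison of both clones asked what became of ZEB1 binding when the repeated region upstream of the miR-200 genes was targeted. The strongest WT clone peak with no counterpart in the delta-Repeat clone lay on chromosome 1 from 1058493 to 1060002. It had a fold of 45.7 and a −log10 q of 188, and had rank 5 among the 1515 WT clone peaks. The same place carried the second strongest peak of unmodified MiaPaCa2 cells (1058354 to 1060112, fold 105) and the strongest peak of RKO cells (1057959 to 1060332, fold 108). The nearest delta-Repeat clone peaks ended at 1003417 and began at 1207902. The stretch of 204 kb between them lacks delta-Repeat clone peaks by definition, so its length does not measure a region of lost binding. It held 2 WT clone, 8 unmodified MiaPaCa2 and 16 RKO peaks, so the WT clone also lacked most of the MiaPaCa2 peaks there. The other WT clone peak in this stretch lay from 1111748 to 1112131, with a fold of 14.6 and rank 174. A CTCF peak of unmodified MiaPaCa2 cells (1057136 to 1057841, fold 19.8) ended 512 bp before the start of the ZEB1 peak. The labels give no coordinates for the edit. In the gene order of GRCh38.p14, MIR200B, MIR200A and MIR429 follow each other on chromosome 1 between MIR200BHG and TTLL10-AS1, and the distance from the peak to these genes was not measured here.

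**Figure D1:**
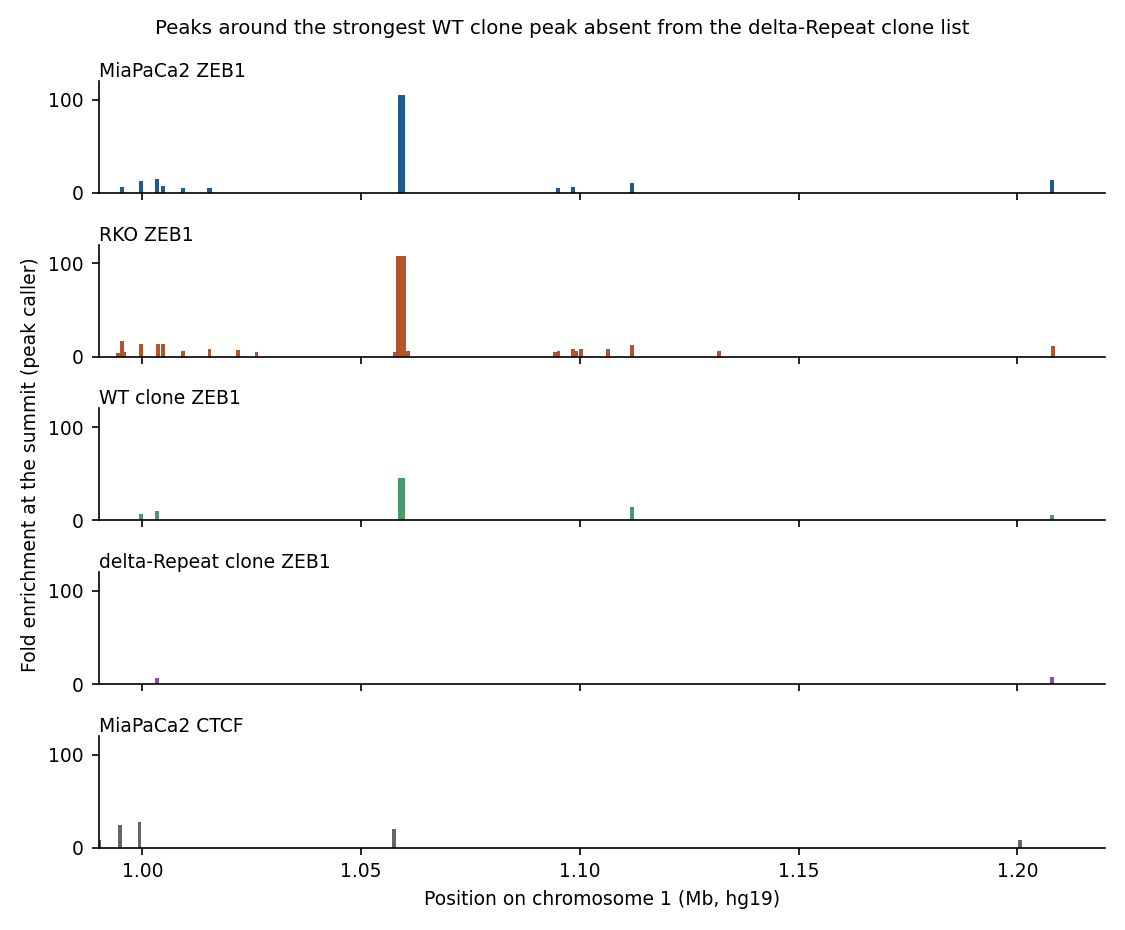
Peaks of the 5 lists on chromosome 1 around the missing peak, with position in Mb (hg19) on the horizontal axis and the peak caller's fold enrichment on the vertical axis, and narrow bars widened to be visible. The tall peak has a fold of 105 in MiaPaCa2, 108 in RKO and 45.7 in the WT clone, and the delta-Repeat clone row shows none there.

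Apart from this place, strong WT clone peaks were found in the delta-Repeat clone. Of the 100 strongest WT clone peaks 99 were shared, and of the 100 strongest delta-Repeat clone peaks 100 were in the WT clone list. The next strongest WT clone peak without a counterpart (chromosome 2, 120996939 to 120997464) had a fold of 16.4 and rank 132. Over the whole lists, 1112 of 1515 WT clone peaks were in the delta-Repeat clone list (73.4%, 95% interval 71.1 to 75.6), where random placement gave a mean of 1.06. In the other direction 1108 of 2160 delta-Repeat clone peaks were shared (51.3%, 49.2 to 53.4). Sharing rose with strength. It went from 53.8% (48.7 to 58.9) in the weakest fold class of the WT clone to 96.6% (94.2 to 98.2) in the strongest, and from 21.7% (18.3 to 25.4) to 91.1% (88.4 to 93.4) in the delta-Repeat clone. Stronger peaks were also wider, with a median width of 242 bp in the weakest and 524 bp in the strongest fold class of the WT clone. With summits within 100 bp, a rule that does not depend on width, the shares still rose, from 35.4% (30.5 to 40.4) to 80.2% (75.8 to 84.1) and from 14.3% (11.4 to 17.5) to 73.0% (69.0 to 76.7). The strongest delta-Repeat clone peak absent from the WT clone list lay on chromosome 2 from 238498706 to 238500028, with a fold of 18.0 and rank 138.

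Most clone peaks overlapped peaks of the unmodified line. The MiaPaCa2 list contained 1442 of the 1515 WT clone peaks (95.2%, 94.0 to 96.2) and 1871 of the 2160 delta-Repeat clone peaks (86.6%, 85.1 to 88.0). With an overlap of 50% of both peaks the shares were 63.8% and 61.9%, and with lists of equal length 72.3% and 68.0%. The peak with the second highest fold of the WT clone was an exception. It lay on chromosome X from 77359211 to 77359964 with a fold of 72.1, was also the ninth strongest of the delta-Repeat clone with a fold of 39.4, and was absent from both lists of unmodified cells. A peak on chromosome 15 from 68132259 to 68132754 (WT clone fold 30.0, delta-Repeat clone fold 11.3) was in the RKO list and absent from that of unmodified MiaPaCa2 cells. Whether the reads under these 2 peaks came from the chromosomes themselves was not examined here.

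Peaks found in a single clone were unevenly spread over the chromosomes. Of the unmodified MiaPaCa2 peaks, 1085 were found in exactly 1 clone, and 333 of these (30.7%, 28.0 to 33.5) were in the WT clone. On chromosome 10 the WT clone held 36 of 48 (75.0%, 60.4 to 86.4) and on chromosome 1 it held 57 of 99 (57.6%, 47.2 to 67.5), against 25.6% (22.8 to 28.5) over the chromosomes other than these. In Fisher's exact tests of each of the 23 chromosomes against all others, the adjusted p was 2.84e-09 for chromosome 10 and 9.26e-08 for chromosome 1. Chromosome 2 had 19.1% (12.2 to 27.7) in the WT clone and an adjusted p of 0.0351 in the exact test against all others. Its interval includes the 25.6%, and against the chromosomes other than 1, 2 and 10 the exact test gave a p of 0.104. The Mantel-Haenszel odds ratio over fold classes was 8.53 (4.36 to 16.7) for chromosome 10 and 3.92 (2.56 to 6.00) for chromosome 1. These tests compare 2 peak lists, not clones in general.

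**Figure D2:**
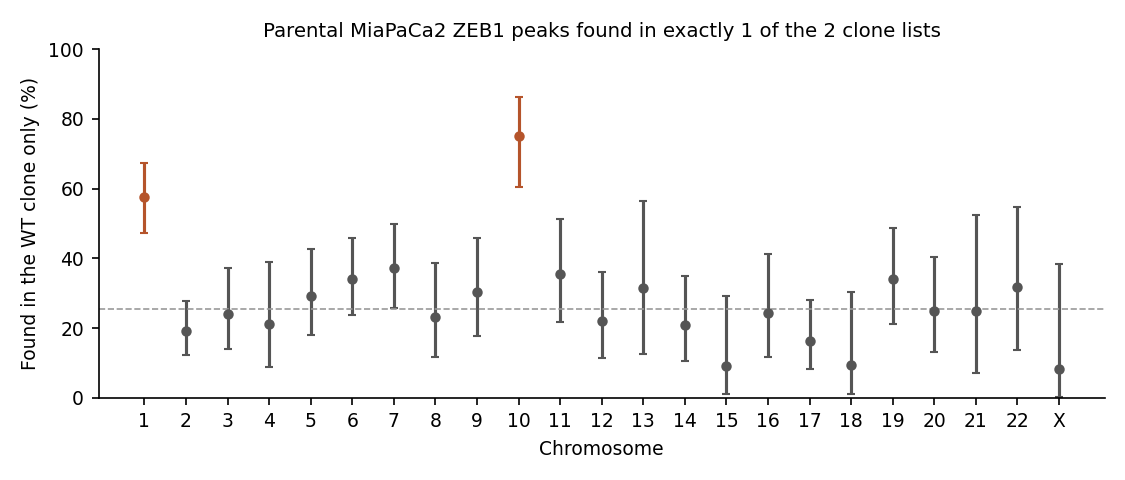
Share of unmodified MiaPaCa2 ZEB1 peaks found in exactly 1 clone that were in the WT clone (vertical axis, %), by chromosome (horizontal axis), with 95% Clopper-Pearson intervals. The dashed line is the 25.6% of the chromosomes other than 1 and 10, which are drawn in orange at 57.6% and 75.0%.

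The comparison of the pancreatic and the colon line asked how far ZEB1 occupied the same places in both. Of the MiaPaCa2 peaks, 2756 of 4804 were in the RKO list (57.4%, 56.0 to 58.8), and of the RKO peaks 2810 of 7193 were in the MiaPaCa2 list (39.1%, 37.9 to 40.2). Random placement gave a mean of 12.4 shared MiaPaCa2 peaks and none of the 1000 placements reached the observed number (permutation p = 0.001, the smallest they can give). Shared peaks were the stronger ones. In the weakest fold class of MiaPaCa2 41.4% (38.6 to 44.2) were shared and in the strongest 84.2% (82.0 to 86.2), and of the 100 strongest 99 were. Median width was 261 bp in the weakest and 678 bp in the strongest class. Summits of overlapping peaks lay a median of 70 bp apart. When summits had to lie within 100 bp, the shares fell to 36.9% of MiaPaCa2 and 24.7% of RKO peaks, and for MiaPaCa2 rose from 22.6% (20.2 to 25.0) in the weakest to 62.8% (60.0 to 65.5) in the strongest class.

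**Figure D3:**
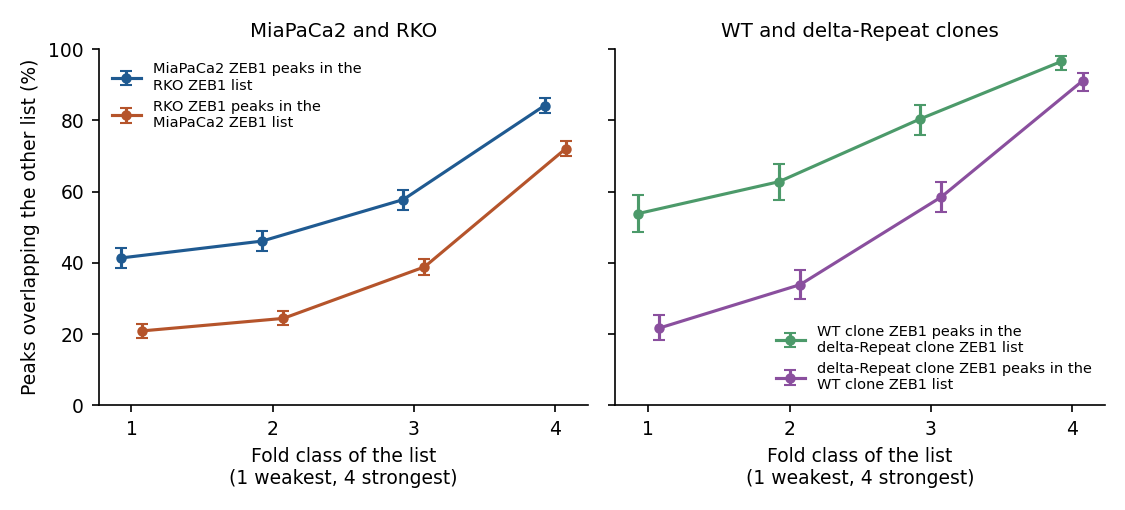
Share of peaks that overlap the other list (vertical axis, %) by fold class from 1, the weakest, to 4, the strongest (horizontal axis), for both cell lines on the left and both clones on the right, with 95% Clopper-Pearson intervals. All series rise, as peak width also does, for MiaPaCa2 from 41.4% to 84.2% and for the WT clone from 53.8% to 96.6%.

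Some strong peaks belonged to a single line. The strongest RKO peak absent from MiaPaCa2 lay on chromosome 9 from 16058168 to 16058821, with a fold of 57.1 and rank 8 of the RKO list. The next 4 lay on chromosome 8 (1805888 to 1807110, fold 40.4), chromosome 1 (233759859 to 233760483, fold 31.8), chromosome 11 (22850843 to 22851396, fold 29.1) and chromosome 1 (28286051 to 28287297, fold 27.2). None of these 5 was in a clone list either. The strongest MiaPaCa2 peaks absent from RKO had lower ranks. They lay on chromosome 2 (121781663 to 121782857, fold 34.5, rank 66), chromosome 2 (224702206 to 224702919, fold 27.3), chromosome 10 (95198426 to 95199336, fold 26.8), chromosome X (18371645 to 18372436, fold 22.6) and chromosome 2 (235150408 to 235151058, fold 22.2), and all 5 were in both clone lists. Among the joined regions, 4246 were in RKO alone, 1473 in unmodified MiaPaCa2 cells alone, 37 in the WT clone alone and 167 in the delta-Repeat clone alone. A further 159 were in all 3 MiaPaCa2 lists and not in RKO.

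ZEB1 and CTCF met at a minority of ZEB1 peaks. In unmodified MiaPaCa2 cells 971 of 4804 ZEB1 peaks overlapped a CTCF peak (20.2%, 19.1 to 21.4). Random placement gave a mean of 49.4 (permutation p = 0.001, the smallest that 1000 placements can give). Random places were spread evenly over whole chromosomes. The excess therefore does not show a preference of ZEB1 for CTCF sites over other sites that yield peaks. The share was 16.9% (14.8 to 19.1) in the weakest fold class and 22.4% (20.1 to 24.9) in the strongest, where peaks were wider. With summits within 100 bp it was 5.91% (4.65 to 7.40) and 7.33% (5.92 to 8.95), so a rise with strength was not detectable apart from width. Neither of the 2 strongest ZEB1 peaks overlapped a CTCF peak, while those on chromosome 1 (89990490 to 89991343, fold 71.4), chromosome 5 (138088118 to 138089045, fold 60.6) and chromosome 12 (32552322 to 32553653, fold 58.8) did. The CTCF peaks there had folds of 5.45, 6.39 and 18.2 and −log10 q values of 7.97, 8.85 and 46.4, so those on chromosomes 1 and 5 lay under the stricter threshold. Summits of overlapping ZEB1 and CTCF peaks lay a median of 155 bp apart, and 16.1% were within 50 bp, against 40.6% between ZEB1 in MiaPaCa2 and in RKO. The share depended on the rule. It was 8.53% for 50% of both peaks, 7.06% for summits within 100 bp and 5.87% with the CTCF list shortened to the length of the ZEB1 list.

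The RKO peaks that MiaPaCa2 lacked met CTCF sites of MiaPaCa2 less often. Of the RKO peaks shared with MiaPaCa2 20.5% overlapped a CTCF peak, and of the unshared 11.1% did (odds ratio 2.07, adjusted p = 9.62e-27, Fisher's exact test over 4 lists). For MiaPaCa2 peaks the shares were 20.4% and 20.0% (odds ratio 1.03, adjusted p = 0.878, the same exact test). Shared RKO peaks were also stronger than unshared ones, with median folds of 7.56 and 5.55. Of the RKO peaks, 13.2% (11.7 to 14.9) overlapped a CTCF peak in the weakest fold class and 19.3% (17.5 to 21.2) in the strongest. Strength was not held constant in the comparison of shared and unshared RKO peaks. CTCF was not profiled in RKO in the samples analysed here.

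ZEB1 peaks were frequent near the ends of chromosomes. The short-arm ends of chromosomes 13, 14, 15, 21 and 22, which are not assembled, were left out. The outer 5 Mb at the other ends make up 6.76% of the sequence and held 20.1% (19.02 to 21.3) of ZEB1 peaks in MiaPaCa2, 24.0% (23.01 to 25.0) in RKO, 24.3% (22.1 to 26.5) in the WT clone and 18.7% (17.0 to 20.4) in the delta-Repeat clone. For CTCF it was 10.7% (10.3 to 11.03). Odds ratios against CTCF ran from 1.92 in the delta-Repeat clone to 2.68 in the WT clone, and the largest adjusted p of the 4 was 4.39e-26 (Fisher's exact test over 12 tests). The MiaPaCa2 share was above that of CTCF on 23 of 23 chromosomes, and the RKO share on 22 of 23. In MiaPaCa2 the share was 15.8% (13.8 to 18.0) in the weakest fold class and 27.0% (24.5 to 29.6) in the strongest. In the delta-Repeat clone it was 12.2% (9.58 to 15.3) and 24.6% (21.1 to 28.5). For RKO, with 22.8% (20.9 to 24.9) and 26.8% (24.8 to 28.9), and the WT clone, with 20.8% (16.9 to 25.3) and 29.6% (25.0 to 34.4), the intervals overlapped. With peaks less than 1 kb apart joined, the share over all classes was 19.7% for ZEB1 in MiaPaCa2 and 10.5% for CTCF.

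**Figure D4:**
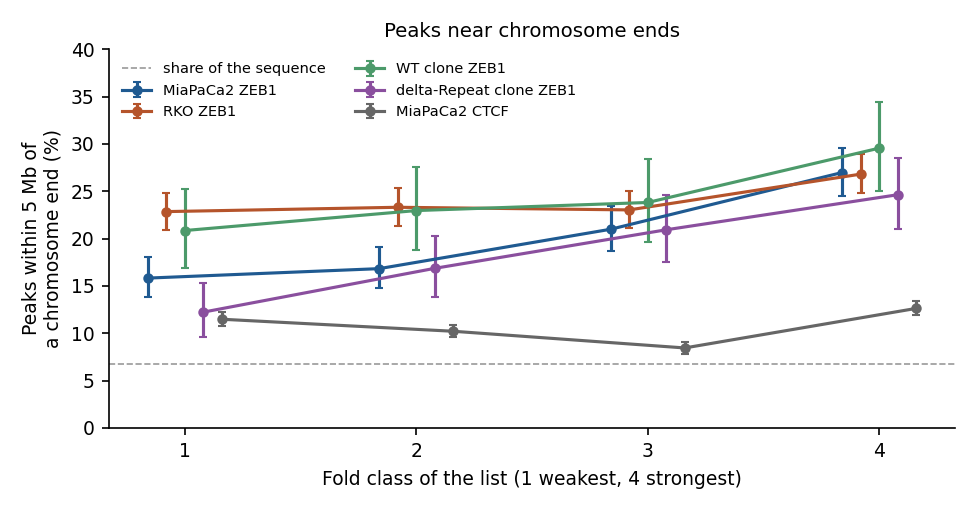
Share of peaks within 5 Mb of a chromosome end (vertical axis, %) by fold class from 1, the weakest, to 4, the strongest (horizontal axis), for the 5 lists with 95% Clopper-Pearson intervals. The dashed line is the 6.76% of sequence that lies there, and ZEB1 in MiaPaCa2 rises from 15.8% to 27.0%. ZEB1 in RKO goes from 22.8% to 26.8%, with overlapping intervals.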

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

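No paired analysis was possible because each group has 1 sample. Joining nearby peaks, leaving out chromosomes 1 and 10, circular shifts, other distances from chromosome ends the threshold on peaks found in a single clone, the reference for chromosome 2 and rules free of peak width were chosen after seeing the data. Shares that left their 95% interval are given here, and no difference past its test's threshold reversed in any setting run. With the stricter threshold, 60.3% of MiaPaCa2 peaks were in RKO and 41.7% the other way, 55.8% of delta-Repeat clone peaks were in the WT clone and 93.5% of WT clone peaks in MiaPaCa2. It left 2013 MiaPaCa2, 2949 RKO, 786 WT clone and 1057 delta-Repeat clone peaks. With 50% of both peaks, the shares were 41.9% of MiaPaCa2 in RKO, 28.0% of RKO in MiaPaCa2, 62.6% of the WT clone in the delta-Repeat clone, 43.9% the other way, 63.8% and 61.9% of these clones in MiaPaCa2, and 8.53% of ZEB1 with CTCF. With summits within 100 bp they were, in that order, 36.9%, 24.7%, 54.7%, 38.3%, 67.1%, 58.7% and 7.06%, and with equal list lengths 49.1%, 49.1%, 64.9%, 64.3%, 72.3%, 68.0% and 5.87%. Joining peaks gave 59.3% of MiaPaCa2 in RKO, 41.7% the other way and 21.98% with CTCF, and leaving out chromosomes 1 and 10 gave 77.1% of the WT clone in the delta-Repeat clone. Asking for 50% of both peaks removes overlaps by construction. For equal list lengths only the longer list was cut, to its peaks of highest −log10 q. Where this was the second list, the share could only fall, by construction. Where it was the first list, its peaks of lower −log10 q were left out and the share rose. The stricter threshold raised some shares and lowered others, and for it and the remaining settings the cause was not tested. The difference on chromosome 2 was lost against the chromosomes other than 1, 2 and 10 (26.4% there, exact p = 0.104), and the rise of CTCF overlap with ZEB1 strength fell from 5.50 to 1.42 percentage points with summits within 100 bp. The odds ratio of CTCF overlap for shared RKO peaks was 2.17 with summits within 100 bp and 1.92 over width classes. Including these odds ratios, 10 planned and 42 added values stayed within their interval, within 1.5 times the count, within the random range or on the same side of the test. Among them, the missing WT clone peak began at 1058493 in all 5 settings tried. None of these settings could have given this peak a match, as the nearest delta-Repeat clone peaks lay 55.1 and 148 kb away. The outcome could change only if a stronger WT clone peak lost its match. The alternatives on gene position, motifs, motif arrays and gene lists near peaks were not run. Unknown read depth limits every statement on absent peaks.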

Other observations

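The ZEB1 lists of both cell lines differed in where their peaks gathered. RKO had a larger share of its peaks than MiaPaCa2 on 5 chromosomes and a smaller share on 7, each with an adjusted p under 0.05 in Fisher's exact tests of 23 chromosomes. These tests take peaks as independent, although many places are in both lists and peaks gather in dense windows. Copy number and read depth of both lines are unknown here. On chromosome 19 the shares were 8.27% in RKO and 5.83% in MiaPaCa2 (odds ratio 1.46, adjusted p = 2.00e-06 in the exact test), on chromosome 9 6.51% and 4.27% (odds ratio 1.56, adjusted p = 9.99e-07), and on chromosome 2 5.10% and 7.70% (odds ratio 0.644, adjusted p = 2.42e-07). The densest 1 Mb window of RKO, on chromosome 9 from 139 to 140 Mb, held 70 RKO and 23 MiaPaCa2 peaks. On chromosome 3 from 189 to 190 Mb, MiaPaCa2 had 23 peaks, the WT clone 6 and the delta-Repeat clone 5, while RKO had 0. On chromosome 2 from 235 to 236 Mb, MiaPaCa2 had 12 peaks and each clone 9, while RKO had 1. MiaPaCa2 peaks shared with RKO lay near chromosome ends more often than the unshared, with 24.1% (22.5 to 25.7) and 14.8% (13.3 to 16.5) within 5 Mb, whereas for RKO peaks both shares were 24.0%. The shared MiaPaCa2 peaks were also stronger, with median folds of 7.61 and 5.90. Strength, with which the MiaPaCa2 share near the ends rose, was not held constant here.

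All tests below were chosen after the results had been seen. The first pattern is the absence of the peak on chromosome 1 at 1058493 from the delta-Repeat clone list. Peaks near the threshold may drop out by chance or depth. In the weakest fold class of the WT clone 175 of 379 peaks were missing, and in the strongest 13 of 379. Of the other 99 among the 100 strongest WT clone peaks 0 were missing (upper bound 3.66%). Such dropout was thus not seen among other peaks of this strength, which argues against it for this peak. Loss of a large part of the short arm of chromosome 1 in all copies should also take the other peaks there. Yet 11 of 12 others of the strongest fold class within the first 10 Mb were kept. The peak not kept lay from 1111748 to 1112131, within the stretch of 204 kb that lacks delta-Repeat clone peaks. Both WT clone peaks of that stretch were thus missing. The 11 kept peaks lay outside it, so they do not test a loss confined to the stretch. For loss in some copies the results point different ways. Without the missing peak, 15 of 17 peaks found in a single clone there (88.2%, 63.6 to 98.5) were in the WT clone, as such loss would give. Yet the 12 peaks, none with a fold above 19.7, were mostly kept, while the missing peak had a WT clone fold of 45.7. That argues against loss in some copies as the whole reason for the missing peak, and its part in the lean stays open. Removal of the bound sequence by the editing may explain the absence. The count of 0 delta-Repeat clone peaks over the widest form of the peak does not test it. The peak was chosen for having no such counterpart, and the nearest delta-Repeat clone peaks lay 55.1 and 148 kb away. Lost binding to an intact sequence would give the same 0, so removal and lost binding cannot be told apart without reads or coordinates of the edit.

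The second pattern is the lean of peaks found in a single clone to the WT clone on chromosomes 1 and 10. Peaks of different strength on these chromosomes do not account for it, since the lower bound of the Mantel-Haenszel odds ratio was 2.56 on chromosome 1, the smaller of both. A change limited to the first 10 Mb of chromosome 1, such as the loss of some copies, may add to the lean there. In these 10 Mb 16 of 18 peaks (88.9%, 65.3 to 98.6) were in the WT clone. The missing peak of the first pattern is among the 16, and without it 15 of 17 were (88.2%, 63.6 to 98.5). Such a change leaves the rest of the chromosome at 50.6% (39.3 to 61.9). Fisher's exact test between both parts, with the missing peak counted, gave p = 0.00318. The window was chosen after that peak had been seen, so this p is no independent support. In the rest, the share was 59.5% (42.1 to 75.2) left of the middle of the chromosome and 43.2% (28.3 to 59.0) right of it. A difference over the whole of chromosome 10, as a copy number difference between the clones would give, may be present: the share was 60.0% (36.1 to 80.9) left of its middle and 85.7% (67.3 to 96.0) right of it, both above 25.6%. Copy number was not measured here, neither clone has an input sample of its own, and clones of 1 line can differ from each other without any edit.

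The third pattern is the strong peak on chromosome X at 77359211, which both clone lists hold and neither list of unmodified cells does. That the peak fell under the threshold in the unmodified cells by chance or depth is argued against by the other peaks of the strongest fold class of the WT clone, of which 2 of 378 were missing from MiaPaCa2 (upper bound 1.90%). The antibody lot, which was used only in the clones, cannot be told apart from the clones themselves, and of the other 99 among the 100 strongest WT clone peaks 1 was missing from MiaPaCa2, the peak on chromosome 15 at 68132259. Sequence brought into the clones with the plasmids may also give such peaks, because plasmids can carry pieces of human promoters that align to their place of origin; 10 WT clone peaks were in both clone lists and in neither unmodified list, and the highest fold among the others was 10.4. The same origin stays open for the peak on chromosome 15, although the RKO list holds it too, and reads across plasmid junctions, which would decide, were not analysed here.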
